A study of Mus musculus with 4 samples.

How the data were processed

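The samples were chromatin from mouse embryonic fibroblasts (MEFs), primary cells taken from C57BL/6 embryos at embryonic day 13.5 and used at passage 4. Protein and DNA were fixed with 2 cross-linkers, ethylene glycol bissuccinimidylsuccinate and formaldehyde, sheared, and sequenced either after chromatin immunoprecipitation (ChIP-seq) or directly as input. There were 4 samples. A pRb immunoprecipitate and an input came from asynchronously proliferating cells grown in 10% serum, and a pRb immunoprecipitate and an input came from cells arrested for 72 hours in 0.1% serum. The labels list several antibodies to pRb, the retinoblastoma tumour suppressor protein, without saying whether they were pooled. All 4 samples carry the label KO, and the labels do not name the gene that was knocked out. The titles of all 4, inputs included, also contain Rb, without saying whether this is the gene knocked out or the target of the antibodies. Whether the cells still made pRb is therefore not given in the sources used here; if they did not, the peaks and their overlaps describe background recovery of chromatin. Samples were grouped by their titles, which leaves 1 library per group. The inputs, like the wild-type reference that the series design mentions, were not analysed here.

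The authors deposited 1 peak list for each immunoprecipitate. Per the submitters' processing notes, Bowtie2, MACS2, HOMER and bedtools were used with the build mm9. Their versions and settings, the use of the input as a control, and the treatment of duplicate reads are not given in the sources used here. Each deposited list has 5 columns and no header: chromosome, start, end, a peak name beginning with MACS, and a score. The deposited score is the authors' own value for each peak, with a scale that no label or header states. Its minimum was 20.0 in both lists. In the report, scores were used to rank, describe and filter peaks within a list, and the numbers of peaks that a filter left were then compared. The build was checked against the coordinates: the last peak on chromosome 1 ended at 197167969 in the proliferating list and at 197194367 in the arrested list. Coordinates are mm9 as in the deposited files, written 1-based. No mm9 gene or repeat annotation was used here, so peaks are given by position, and the comparisons planned for promoters, gene lists and repeat classes were not run.

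The comparisons, the rule for named peaks and most alternatives were fixed before the data were examined. Peaks within a list never overlapped, so merging left both lists as they were. Overlap meant at least 1 shared base pair. The overlap that list size and peak width give by themselves was measured with 100 random placements of the peaks on their own chromosome, between the first and last peak of either list, with each peak's width kept. Placements for width classes numbered 20. Placed peaks can fall into assembly gaps and repeats to which no read maps, and they can overlap each other. Chromosome length was taken as the largest peak end in either list. Windows were 1 Mb. Score ties were broken at random with a fixed seed when the upper part of a list was taken. The peaks named in the text are the 10 with the highest score in each list, with ties ordered by position, and the 5 shared peaks whose lower rank in the 2 lists is best; the windows named are the 5 with most peaks in each list. Intervals of shares are 95% Wilson intervals. They and the limit for a count of 0, which is 3 counts of the total, cover counting error only. With 1 library per growth condition, the difference between conditions has no replicate check and no p-value is given for it.

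Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures used matplotlib 3.10.9. The overlap code was tested on simulated lists of the real size and widths. With 0%, 5% and 20% of the 109740 proliferating peaks placed on arrested peaks, it recovered 0.135%, 5.07% and 20.3%, and for 300 peaks per simulation each call matched a plain comparison with every interval. In the closing section, scores are read as tag counts and compared between lists, a reading that no label or header states. The code for it recovered the simulated window widths of 150 and 260 bp. For 42082 simulated peaks narrower than the window, whose tags were scaled up to the window, it recovered the right number of tags in 100.0%. That step started from the scaled counts and not from scores. The whole path from score to tags in such narrow peaks was therefore not simulated. The lists hold no read counts, so the depth behind each peak is not given directly. The alternatives were the upper 50% and 10% of each list by score, autosomes and X alone, peaks merged within 1000 bp, stricter overlaps, placement only in 1 Mb windows that hold peaks, an arrested list reduced to the size of the proliferating one, other numbers of top peaks, and 100 kb windows. Chosen after seeing the data were a score of at least 50, moves of each peak by 5 to 50 kb, lists without peaks of at least 1000 bp, windows without the sparse ones, and covered bases in place of peaks for the X chromosome.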

Results

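Chromatin recovered with antibodies to pRb, a protein that represses E2F-driven cell cycle genes when it is not phosphorylated, was profiled by ChIP-seq in fibroblasts labelled KO, in 2 growth conditions. The proliferating cells were grown in 10% serum and the arrested cells were held in 0.1% serum for 72 hours. Each condition was represented by 1 immunoprecipitated library and its deposited peak list. The labels do not say which gene was knocked out, so whether the cells had pRb is not given in the sources used here, and the peaks are described here as calls rather than as sites bound by pRb. The series title names silencing of endogenous retroelements in somatic cells as its subject. The comparison open to these lists is where peaks were called in cells labelled KO in each growth state, and how far the calls coincided.

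Far more of the genome was called as peaks in arrested than in proliferating cells. The arrested list held 699290 peaks and the proliferating list held 109740, a ratio of 6.37. Arrested peaks covered 161 Mb, or 6.25% of the 2581 Mb spanned by the lists, and proliferating peaks covered 18.0 Mb, or 0.697%. The distance from one peak to the next had a median of 2303 bp in arrested cells, with quartiles of 996 and 4611 bp. In proliferating cells the median distance was 15338 bp, with quartiles of 6229 and 31487 bp. The deposited scores are the authors' own values for each peak, on a scale that is not given in the sources used here. Both lists started at a score of 20. The median was 24.3 in proliferating cells (quartiles 22.1 and 30.4), so most of that list lay close to its lowest score, and 97.5 in arrested cells (quartiles 71.0 and 153). Keeping the peaks with a score of at least 50, a limit chosen after seeing the data, left 1838 proliferating (1.67%) and 596750 arrested peaks (85.3%), and the ratio of their numbers moved from 6.37 to 325. The scores were not shown to have the same scale in both lists. These values compare 2 libraries. Whether the difference exceeds the spread between cultures could not be assessed, because no condition had a second library.

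Peaks were narrow in both conditions. The median width was 153 bp in proliferating cells, with quartiles of 135 and 186 bp, and 166 bp in arrested cells, with quartiles of 152 and 296 bp. The narrowest arrested peaks measured exactly 144 bp, and 82210 of them (11.8% of the list) had that width. The narrowest proliferating width was 62 bp, shared by 122 peaks (0.111%). Scores repeated often: the 20 commonest values accounted for 54.3% of arrested and 31.1% of proliferating peaks.

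**Figure D1:**
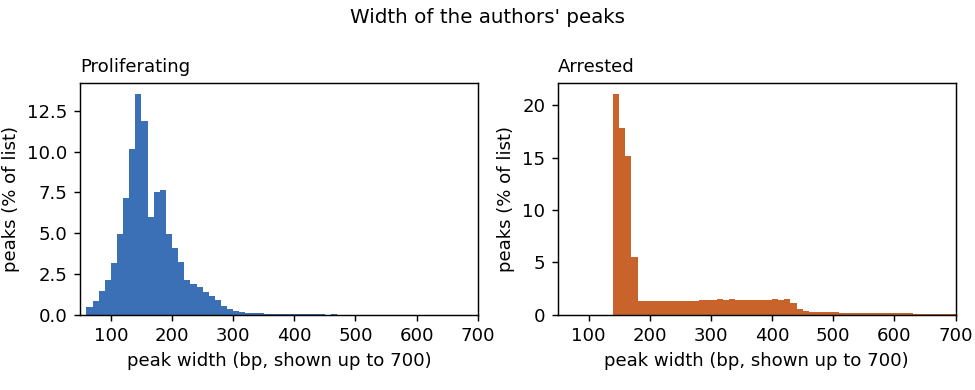
Distribution of peak width in base pairs (x axis, up to 700 bp) as a percentage of each list (y axis) for the proliferating library (left) and the arrested library (right), in bins of 10 bp. The arrested widths start at 144 bp and have a median of 166 bp, and the proliferating widths start at 62 bp and have a median of 153 bp.

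Calls were spread over the autosomes at nearly even density. Across the 19 autosomes, arrested cells had 266 peaks per Mb, from 245 on chromosome 7 to 276 on chromosome 6. Proliferating cells had 42.0 per Mb, from 36.4 on chromosome 7 to 45.3 on chromosome 2. The densest autosome thus exceeded the sparsest by 1.13 times in arrested and 1.24 times in proliferating cells. By number of peaks, the X chromosome was below the pooled autosomes in both lists, at 0.944 of their density in arrested cells (95% interval 0.935 to 0.954) and 0.844 in proliferating cells (0.822 to 0.866). The intervals cover counting error only. Densities were not adjusted for copy number, repeat content or how well reads map, which differ between chromosomes. With 251 peaks per Mb, the arrested X lay within the range of single autosomes, above chromosome 7, and the proliferating X, with 35.4, lay below each of them. By covered bases, a measure chosen after seeing the data, the arrested X was not lower, at 1.004 times the autosomes, and the proliferating X was at 0.856. The Y chromosome held 71 arrested and 3 proliferating peaks, 0.0920 and 0.0246 of the autosomal density over the 2.90 Mb in which peaks were called. Densities of the lists went together across autosomes (Pearson r = 0.84, Spearman rho = 0.69). The two-sided permutation p was 1e-05, the smallest that 100000 permutations can give, and 0.0016. Benjamini-Hochberg adjusted values were 2e-05 and 0.0016, over these 2 measures of the same relation. Without chromosomes 7 and 12, the farthest from the median, Pearson's r was 0.71. With the sparse windows defined below left out, r was 0.73 and rho was 0.72 across the 19 autosomes. Both densities were divided by the same lengths, which include sequence to which no read maps. Shuffling chromosomes does not allow for this, so the p-values cannot separate shared placement of peaks from shared limits of mapping. Chromosomes are not replicates.

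**Figure D2:**
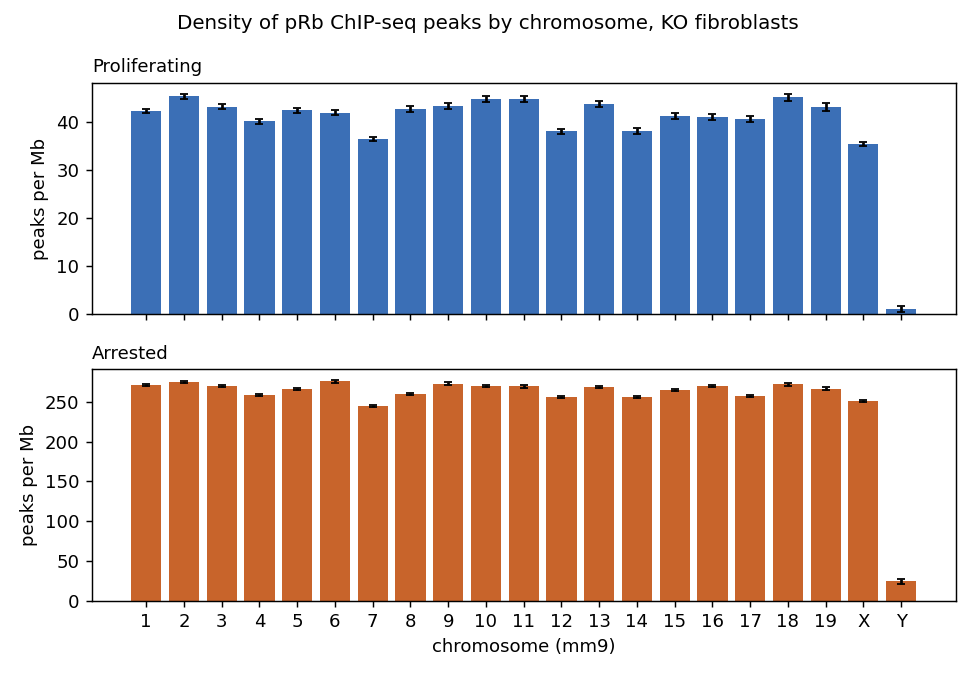
Peaks per Mb (y axis, from 0) on each mm9 chromosome (x axis) in the proliferating library (top) and the arrested library (bottom). Bars are densities from 1 list each, and error bars are the Poisson standard deviation of the count, which covers counting error only. Autosomes lie between 36.4 and 45.3 per Mb in proliferating and between 245 and 276 per Mb in arrested cells, with X lower than the autosomal average in number of peaks and Y far below.

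Within chromosomes, a few megabases stood out in both lists. The window from 146 to 147 Mb on chromosome 4 held 121 proliferating and 370 arrested peaks, and its neighbour from 145 to 146 Mb held 96 and 370. The window from 30 to 31 Mb on chromosome 17 held 86 and 369. These compare with medians of 43 proliferating and 276 arrested peaks per window. The 3 windows were among the 5 densest of each list. The other 2 of the 5 densest in proliferating cells lay on X, from 4 to 5 Mb with 88 peaks and from 31 to 32 Mb with 85. The same X windows had 186 and 149 arrested peaks, ranks 2506 and 2521 among 2584 windows. Those ranks are by number of peaks and not by covered length. Arrested peaks covered 124 and 81.3 kb there, more than in the chromosome 16 and 11 windows named next (76.0 and 73.2 kb). In arrested cells the remaining 2 were on chromosome 16, from 43 to 44 Mb with 352 peaks, and on chromosome 11, from 36 to 37 Mb with 347. Their proliferating counts were 49 and 43.

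Of the 50 densest windows of each list, 5 were the same, where independent lists would share 0.967. Across all windows, ranks of peak density in one list had little relation to those in the other. The Spearman correlation across the 2584 windows was 0.07 and the Pearson correlation 0.36. Without the windows holding fewer than 50% of the median arrested count, which left 2529, these were 0.01 and 0.09. Among those 2529 windows the standard deviation of counts was 25.7 around a mean of 275 in arrested cells and 10.3 around a mean of 43.1 in proliferating cells. A Poisson scatter would give 16.6 and 6.57. Windows are not independent replicates.

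The peak sets coincided only slightly more often than randomly placed peaks. Of the proliferating peaks, 12738 of 109740 (11.6%, interval 11.4 to 11.8) overlapped an arrested peak. Random placement gave 10.7% ± 0.0997 (SD over 100 placements), with a highest value of 10.9%, so the observed share was 1.09 times the random one. Of the arrested peaks, 12727 (1.82%, interval 1.79 to 1.85) overlapped a proliferating peak, against 1.67% ± 0.0155 and a highest value of 1.70% in the placements. The excess in proliferating peaks was 0.922 percentage points. By width, below 150 bp, 10.4% were shared against 9.63% at random, and from 200 bp to below 300 bp, 13.6% against 12.5%. From 300 bp to below 500 bp, 17.2% were shared against 15.4%, and the highest of 20 placements gave as much as observed. At 500 bp and above, 34 of 79 proliferating peaks (43.0%, interval 32.7 to 54.0) were shared, against 26.5% at random and 32.9% in the highest of 20 placements. Among arrested peaks the excess was not seen in each class: from 300 bp to below 500 bp, 2.37% of 149704 were shared, against 2.29% at random and 2.38% in the highest placement. The 15 proliferating peaks of at least 1000 bp showed no such excess, with 6 shared (interval 19.8% to 64.3%) against 42.7% at random.

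**Figure D3:**
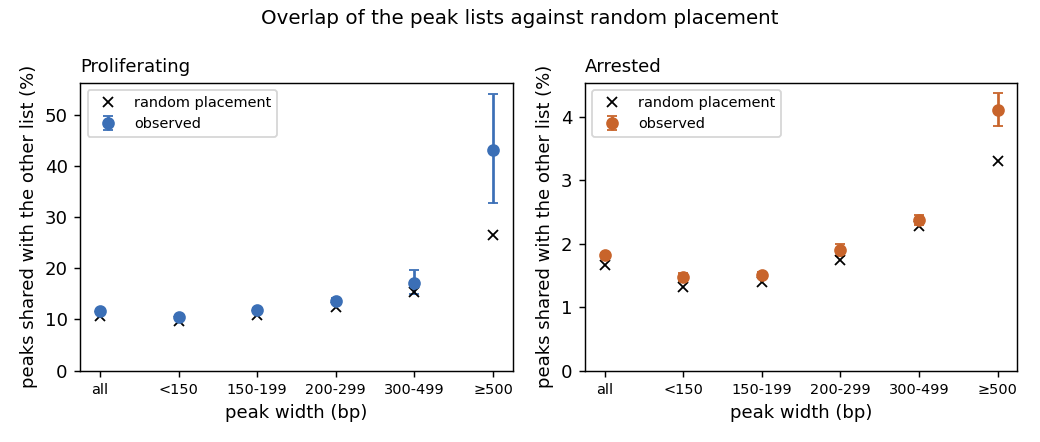
Share of peaks that overlap the other list by at least 1 bp (y axis, from 0, different scales) for all peaks and by peak width in bp (x axis), for the proliferating list (left) and the arrested list (right). Circles are observed shares with 95% Wilson intervals and crosses are means of random placements; overall 11.6% of proliferating peaks were shared against 10.7% at random, and the gap was wider for peaks of 500 bp and above.

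The highest-scoring peaks were too few to compare the top of one list with the top of the other. Among the top 1000 peaks of each list, 0 overlapped each other, which allows a share of up to 0.300%, and random placement gave 0.012%. Among the top 5000 of each, 4 overlapped (0.080%), against 0.058% at random, and 29 of 100 placements gave at least as many. Of the top 1000 proliferating peaks, 113 (11.3%, interval 9.48 to 13.4) overlapped any arrested peak, against 9.18% at random and 11.1% in the highest of 100 placements. Of the top 1000 arrested peaks, 12 (1.20%, interval 0.688 to 2.09) overlapped any proliferating peak, against 1.46% at random. That difference was within counting error, and 77 of 100 placements gave at least as many. Among the top 5000 arrested peaks the direction turned, with 85 (1.70%, interval 1.38 to 2.10) against 1.44% at random, which 3 of 100 placements reached.

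In proliferating cells the highest score, 148.23, belonged to a 78 bp peak on chromosome 13 (5091417 to 5091494). It was followed by a 3228 bp peak on X (123302094 to 123305321, score 137.34) and an 87 bp peak on chromosome 8 (72425033 to 72425119, score 125.18). These 3 overlapped arrested peaks. The other 7 of the top 10 overlapped none. They lay on chromosome 4 at 132514455 (62 bp), chromosome 10 at 57893828 (75 bp), chromosome 13 at 40710181 (64 bp), chromosome 14 at 31783854 (68 bp), chromosome 17 at 16445332 (67 bp), chromosome 8 at 81398129 (74 bp) and chromosome 11 at 87822128 (65 bp). Their scores ranged from 112.33 down to 96.23. Apart from the X peak, each of the top 10 was at most 87 bp wide, below the list's first quartile of 135 bp. In the closing section's reading, scaling to a fixed window raised the scores of such narrow peaks. The peaks were not ranked again without that scaling.

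In arrested cells 3 peaks had the maximum score of 3100. The shared value does not order them, and whether it is an upper limit of the scale is not given in the sources used here. The 3 were a 5182 bp peak on chromosome 1 (24618199 to 24623380), a 600 bp peak on chromosome 17 (4626075 to 4626674) and a 692 bp peak on chromosome 6 (103598689 to 103599380). The next were a 279 bp peak on chromosome 1 (12634752 to 12635030, score 2337.73), a 3340 bp peak on chromosome 2 (22442715 to 22446054, score 2055.88) and a 6297 bp peak on chromosome 17 (39979841 to 39986137, score 1978.71). The top 10 also held a 257 bp peak on chromosome 2 at 125973522, an 828 bp peak on chromosome 11 at 69401927, a 905 bp peak on chromosome 12 at 98299463 and a 266 bp peak on chromosome 6 at 10136288. Only the chromosome 12 peak among these 10 overlapped a proliferating peak. No repeat annotation or list of problematic regions was used here, so whether the top peaks of either list lie in sequence present in many copies was not tested.

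Of the shared peaks, the one whose lower rank in the 2 lists was best was on chromosome 5. It ran from 60433903 to 60434313 in proliferating cells, with a score of 69.37 and rank 128, and from 60433865 to 60434420 in arrested cells, with a score of 514.56 and rank 1137. The next 4 by their lower rank started, in proliferating cells, at 52849672 on chromosome 2, 108747150 on chromosome 13, 26635104 on chromosome 14 and 62570093 on chromosome 15. Their lower ranks in the 2 lists were 3388, 4365, 4490 and 5359.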

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

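With 1 library per condition, no replicate could be left out, and neither promoter nor repeat alternatives were run, for want of an mm9 annotation. Of the alternatives, 50 values stayed within the interval of the reported value (or within 1.5 times it, for counts and lengths), 45 moved and 1 turned: by covered bases the arrested X was at 1.004 times the autosomes, while by number of peaks X stayed below them in each setting run. The order of the median widths also turned in the upper 50% of the lists, and the overlap of the top arrested peaks with proliferating ones was below random for the top 1000 (ratio 0.823) and top 500 (0.504) and above it for the top 5000 (1.18). The overlap of the lists (not of the top peaks alone) stayed above the mean of random placements. Taking the upper 50% by score left, by construction, 54870 proliferating and 349645 arrested peaks; they covered 9.12 and 69.2 Mb, had median widths of 162 and 159 bp, X densities of 0.817 and 0.904 of the autosomal one, shared 5.40% and 0.846%, and gave a Pearson correlation across windows of 0.230. The upper 10% left 10974 and 69929 peaks over 1.62 and 13.0 Mb, with widths of 115 and 157 bp, an arrested X density of 0.931, shares of 0.984% and 0.154%, and a Pearson correlation of 0.0748; there 18 and 21 of 100 placements reached the observed overlap, so with 108 shared peaks the excess over random could not be told from chance. Chosen after seeing the data were the score limit, the moves by 5 to 50 kb, covered bases for X, leaving out peaks of at least 1000 bp and leaving out sparse windows. A score of at least 50 left 1838 proliferating peaks over 0.260 Mb and 596750 arrested peaks over 125 Mb, which moved the ratio of peak numbers from 6.37 to 325, with shares of 9.41% and 0.0293%, and ratios to random placement of 1.15 and 1.17, with 2 placements as high in each list. Merging within 1000 bp raised arrested coverage to 254 Mb, the shares to 15.0% and 2.97%, and the correlations to 0.134 (Spearman) and 0.399 (Pearson). Overlaps of at least 50% of the peak gave 6.92% and 0.628%, and of at least 50% of both peaks 3.58% and 0.561%, the former at 1.11 times random. The arrested list reduced to the size of the proliferating one gave 1.71% in both, with ratios of 1.13 and 1.14. Moving each peak by 5 to 50 kb gave an arrested ratio of 1.07. The Pearson correlation was 0.109 in 100 kb windows and 0.0884 without sparse windows, where Spearman's was 0.0121, so the Pearson correlation of the lists in 1 Mb windows rested largely on sparse windows. For the other moves the cause was not tested. The lists give no read counts, so depth could not be set equal.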

Other observations

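All tests of explanations in this part were chosen after the results were seen, and the one on sites recovered in both libraries was changed from a share to a ratio after its first value was seen, because shares were not adjusted for peak width. The test of a permissive threshold was likewise changed, from a share of arrested peaks to a number, after the share was seen. The interval on chromosome 8 was also chosen after the peaks were seen. Of 15 proliferating peaks of at least 1000 bp, 7 lay between 19 and 21 Mb on chromosome 8, an interval that makes up 0.0775% of the spanned genome, and 3 each lay on chromosome 11 and on X. The widest ran over 3859 bp from 19723688. Arrested cells had 364 such peaks, of which 16 (4.40%) lay in the same interval of chromosome 8; their widest ran over 10736 bp from 20027342. X held 69 of the arrested ones, chromosome 4 held 53 and chromosome 5 held 43. Whether wide peaks cluster beyond chance was not tested. Of the 364, 74 (20.3%, interval 16.5 to 24.8) overlapped a proliferating peak, against 9.89% in the highest of 20 random placements; of the 15 proliferating ones, 6 overlapped an arrested peak, no more than random placement gave (42.7%).

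Scores were read as counts of tags, a reading that no label or header states. They were taken as 10 times the negative log10 of a Poisson tail probability, with a mean equal to one tag density times the peak width or a fixed window, whichever was larger. Within 0.01, 86.9% of proliferating and 83.1% of arrested scores matched such a value, against at most 0.0447% and 1.43% when the density was moved by 5% or 10%. Most scores in each list thus followed one density. Matched peaks do so by definition, so they cannot show whether a local or input-derived mean was also considered. The peaks that did not match, where such a mean could appear, were not examined. Whether the input was used is not given in the sources used here. In this reading the lowest score of 20 is a probability of 0.01, a lenient limit for calls across a genome. The fitted windows were 124 bp and 290 bp, 2 and 2.01 times the narrowest width of each list, and the densities were 0.823 and 0.852 tags per 100 bp. In matched peaks narrower than the window, 99.5% of proliferating and 97.7% of arrested values were whole tags scaled up to the window, against 87.5% and 59.6% by chance. The scaling started from the peak width plus an offset of 4.5 bp in proliferating and 2.5 bp in arrested cells. Each offset was the one, among those tried, that made this percentage highest, and the chance values hold for that offset. The number of tags per peak, with that scaling undone, had a median of 5 in proliferating cells (quartiles 4 and 6) and 12 in arrested cells (quartiles 9 and 16). The arrested peaks so read, 81.6% of that list, held 6.89 times the tags that the background density gives, and the proliferating ones, 86.8% of theirs, held 3.80 times. Peaks were called for exceeding a background, so an excess over it was fixed in advance and is no independent measure of enrichment. Wider peaks held more tags in both lists, with Spearman correlations across peaks, which are not independent replicates, of 0.32 in arrested and 0.57 in proliferating cells. The fewest tags with which a peak could be called rise with its width in this reading, so a positive correlation was in part fixed in advance. With the deposited scores of all peaks, which rise with the scaling in narrow peaks, the correlations with width were -0.43 and -0.08. With scores computed without that scaling, for the peaks read as tags, they were 0.17 in arrested and -0.02 in proliferating cells.

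The arrested list had 6.37 times as many peaks as the proliferating list, while the background densities read from the scores had a ratio of 1.04, which argues against lower depth in the proliferating library, as the caller counted it, as the cause. Scaling raised the scores of 74.4% of the arrested and 13.2% of the proliferating peaks read as tags, and without it 282863 (49.6%) and 626 (0.657%) of these reached 50; the share alone does not decide on a more permissive threshold, but those arrested peaks were still 2.58 times the whole proliferating list, which reached down to 20, so such a threshold is argued against as the whole cause. Of the arrested peaks read as tags, at least 91.2% would still reach a score of 20 in a window of 124 bp. This argues against the wider calling window as the source of most of those peaks. How many peaks the proliferating library would gain in a window of 290 bp cannot be read from its list. The effect of the window on the ratio of peak numbers therefore stays open. Repeated copies of the same fragments were not tested, since the lists hold no reads, and stay open. In this reading the arrested peaks of the narrowest width, 144 bp, held a median of 9 tags (70043 peaks). The narrowest proliferating peaks, 62 bp, held a median of 5 (107 peaks). Whether the tags in such peaks lay at repeated positions cannot be told from the lists. Growth arrest also stays open and untested, because each condition had 1 library.

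The overlap slightly above random placement, 1.09 times, was not a matter of broad unevenness alone: moves of each proliferating peak by 5 to 50 kb left a ratio of 1.07, and none of the 100 moves reached the observed share. It was not a matter of very wide peaks alone either, since the ratio was 1.08 without peaks of at least 1000 bp. Sites recovered in both libraries could raise the overlap at high scores, but the top peaks leave this open: for the top 500, 1000 and 5000 the ratios were 1.29 (interval 1.01 to 1.64), 1.23 (1.03 to 1.46) and 1.12 (1.04 to 1.21) in proliferating and 0.504 (0.196 to 1.28), 0.823 (0.472 to 1.43) and 1.18 (0.955 to 1.45) in arrested cells, and each interval includes the 1.09 of all peaks. The top peaks were taken by deposited score, which scaling raises in narrow peaks, and were not ranked again by tags. Fine-scale differences in how well reads map were not tested. No test here separates specific from unspecific recovery of chromatin, and the labels leave open whether these cells had pRb; without it, each peak count and overlap here would describe background recovery.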
